A study of Mus musculus with 6 samples.

How the data were processed

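RNA abundance was measured on 6 Affymetrix Mouse Genome 430 2.0 arrays, which carry short oligonucleotide probe sets against mouse transcripts. Per the labels, the cells were R1 mouse embryonic stem cells, infected with a lentivirus expressing a short hairpin RNA (shRNA) and sorted for GFP; 3 arrays came from cells with an shRNA against luciferase, the control, and 3 from cells with the first shRNA against KIAA1718. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says that the replicates came from separate infections or cultures, so p-values measure only the spread between these samples, which may be technical.

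The deposited table holds the authors' linear signal intensity for each probe set. GCOS is named as the software, per the submitters' processing notes, and its version, algorithm and settings are not given in the sources used here. Detection calls and scanner files were not used here. The deposited intensities did not share a scale: the mean signal after trimming 2% of probe sets at either end ran from 61.5 to 81.5 across arrays, and the median signal from 9.58 to 13.3. The plan made before the data were examined had assumed scaled signals and no further normalization. Because of this spread, quantile normalization between arrays was used in its place, a choice made from the array scale, and the unscaled values were kept as an alternative. Signals quoted in the text are the deposited intensities, not scaled between arrays, and fold changes come from the normalized values.

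A pseudocount of 16 was added before taking log2, so fold changes are on the log2(signal + 16) scale and understate the change of genes with low signal. The 64 AFFX control probe sets and the 40% of probe sets with the lowest mean over all 6 arrays were left out, which kept 27022 probe sets. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values of genes come from limma. Of the 45037 probe sets without controls, 34945 had 1 gene symbol in the array's annotation, 932 had several and 9160 are unnamed here. Symbols were updated through the Entrez gene number with a RefSeq gene table of the GRCm38.p6 assembly, which also gave each gene's chromosome and neighbours. No genome build is named with the intensities, so no coordinates are given. Each of 12741 genes was represented by its probe set with the highest mean over all 6 arrays among those with 1 symbol. Of 332 changed genes with a further tested probe set, 286 had all further probe sets on the same side, and none had a further probe set past the threshold on the opposite side.

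Gene lists, 29 in number and holding 824 symbols of which 755 were on the array, were fixed before the data were examined. They were tested with camera at its preset correlation of 0.01, with the correlation estimated from the data beside it, and with fry; chromosomes were tested with camera in the same way. Counts within a list are given after adjustment over all probe sets and adjusted over the list alone. The genes named are the target; Fgf4, Pou5f1, Nanog and Sox2; the 12 with the largest increase and the 12 with the largest decrease among genes past the threshold whose groups did not overlap; and up to 4 members of each list past the threshold with the largest change, or up to 2 with the smallest p where fewer than 2 passed. Krt7, Uba1y, Orly, Ifih1, Ddx58, Eif2ak2, Oas1a, Oasl2, Gata6, Gata4, Sox17, Otx2, Fgf5 and Dnmt3a, outside this rule, were named after their values were seen. RIKEN clones and numbered gene models were counted and not named. Exact permutation tests of 3 against 3 arrays are two-sided and cannot give a p below 0.1.

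The replicate numbers are shared by both groups. Deviations from the group means correlated at 0.203, 0.125 and 0.132 between arrays numbered 1, 2 and 3, against -0.150 to 0.0234 for arrays with different numbers. Deviations cancel within a group, so higher values for equal numbers force lower ones for different numbers, and the contrast is not independent. Each of the 3 correlations was over 0.1, the limit for treating the numbers as pairs. The main fits nevertheless leave the pairing out. Values with the replicate number as a block are given where they change the call of a list, a chromosome or a gene named by the rule. Changed counts within lists are given for most lists. The pairing rests on the data, since no label says what a number marks. No pair of arrays held identical values: at least 45100 probe sets differed in any pair. On data simulated for this comparison over 27022 probe sets, 35.8% of changes of 0.5 (log2) were recovered and 100% of those of 1 and of 1.5, with 14 false calls among 171. Only 67, 67 and 66 probe sets were changed by 0.5, 1 and 1.5. The simulated noise was independent between probe sets, unlike the correlated deviations above, so these rates need not hold for the real arrays. The number of arrays limits the precision.

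Alternatives were a pseudocount of 1 or 64, no filter or a filter of 60%, centring on array medians, no intensity trend, array weights, the replicate block, leaving out each array, a fold of at least 1.5, the mean of all probe sets of a gene, and an estimated correlation for lists and chromosomes. The unscaled values, first planned as the main setting, were kept as an alternative when quantile normalization replaced them; the mean of the fibroblast list as a covariate and leaving out the genes of 6 chromosomes were added after the data were seen.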

Results

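The data set compares R1 mouse embryonic stem cells carrying an shRNA against KIAA1718 with cells carrying an shRNA against luciferase, with 3 arrays in each group. KIAA1718 is the protein encoded by Kdm7a, also called Jhdm1d, a demethylase of lysines 9 and 27 of histone H3. The comparison asks which transcripts differ between cells with these shRNAs. Each group carried a single shRNA. Effects of its sequence on other genes, and differences between the infected populations, cannot be told apart from an effect of targeting KIAA1718. Median signals per array ran from 9.58 to 13.3, and correlations between arrays over the tested probe sets were 0.983 to 0.989 within groups and 0.977 to 0.985 between groups. The ratio of 3' to 5' control probe sets, a sign of RNA integrity, was 0.888 ± 0.0138 for Gapdh in controls and 0.884 ± 0.0450 in knockdown cells (SD, n = 3, exact p = 0.9), and 1.46 ± 0.0650 and 1.40 ± 0.0857 for beta-actin (SD, n = 3, exact p = 0.4). The control spikes of knockdown replicate 2 lay 4.32 above its median signal (log2), against 4.81 to 4.95 on the other arrays.

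The targeted gene, Kdm7a (Entrez gene 338523), did not pass the threshold. Its brightest probe set had a signal of 36.5 ± 7.39 in controls and 33.2 ± 8.64 in knockdown cells (SD, n = 3), a log2 difference of -0.20 with a 95% interval of -0.54 to 0.14 and an adjusted p of 0.534; leaving out 1 array gave -0.35 to -0.06. Of its 5 probe sets, 3 had enough signal to be tested, and the other 2 tested ones differed by -0.22 (adjusted p = 0.458) and -0.16 (adjusted p = 0.585). If the signal of the brightest probe set came from Kdm7a alone, halving it would give -0.61, outside the interval, though inside it when luciferase replicate 3 or knockdown replicate 1 is left out. By the same reading the next probe set would give -0.59, outside its interval of -0.45 to 0.14, also when any 1 array is left out, and the dimmest tested one -0.35, inside its interval of -0.53 to 0.10. The target therefore gives no check of the labels on these arrays, and "knockdown" below means the arrays labelled with the KIAA1718 shRNA.

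Between the groups, 612 of 12741 genes changed, 336 higher and 276 lower in knockdown cells, and 64 of them changed at least 2-fold. The largest increases were in Gbp2 and Gbp2b, interferon-inducible GTPases, at 2.22 ± 0.14 and 1.99 ± 0.13 (log2 difference ± SE), and in Snhg14, a long noncoding RNA of the imprinted Snrpn region, at 2.04 ± 0.13. Igfbp3, a secreted binding protein of insulin-like growth factors, rose from a signal of 80.6 ± 16.2 to 354 ± 52.5 (SD, n = 3), and the keratin gene Krt19 from 29.9 ± 5.92 to 159 ± 9.56. The metal ion transporter gene Slc39a8 rose by 1.53, Klhl13 by 1.49, Gbp3 by 1.46, the Y-linked translation factor gene Eif2s3y by 1.41, Pkdcc by 1.41, the polycomb-related Sfmbt2 by 1.40 and the immunoproteasome gene Psmb8 by 1.37. The largest decrease was in Inhbb, which encodes a subunit of activin and inhibin, from 439 ± 135 to 111 ± 23.9 (log2 difference -1.96 ± 0.15). It was followed by the transcription factor genes Tbx3 at -1.63, Tle5, a co-repressor gene, at -1.39, and Tfcp2l1 at -1.22. Cobl fell by 1.22, Parvb by 1.21, Cd99 by 1.19, Esrrb by 1.16, Igsf21 by 1.13, Mras by 1.12, the Wnt receptor gene Fzd5 by 1.10 and the creatine transporter gene Slc6a8 by 1.09. Adjusted p-values of these 24 genes were 0.00958 or lower. All 612 changed genes had groups that did not overlap. Chance gives that for 10% of genes not chosen by a test, but passing the threshold with 3 against 3 arrays nearly requires it. It is therefore no further support. Counted by probe set, 991 of 27022 changed, 523 of them higher. With replicate number as a block, 1005 genes and 1684 probe sets changed, including all 612 and all 991. Higher genes made up 54.9% of the changed ones here and 81.6% of 364 with unscaled values, under which the median difference of all genes was 0.11 (log2); without luciferase replicates 2 or 3 the count was 288 or 167, and without knockdown replicates 1, 2 or 3 it was 392, 316 or 196.

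Of 32 measured members of the list of core and naive pluripotency, 11 fell, 1 rose and 20 did not pass, and adjusted over the list alone 13 fell and 2 rose. Esrrb fell from a signal of 560 ± 105 to 270 ± 74.3 and Tfcp2l1 from 379 ± 31.4 to 177 ± 63.1 (SD, n = 3). Klf4 fell by 0.91. Fgf4, the growth factor gene through which embryonic stem cells signal to themselves, fell from 321 ± 62.9 to 208 ± 11.5, a log2 difference of -0.72 ± 0.10 (adjusted p = 0.00331). Dppa3, a gene of naive cells and germ cells, moved the other way, by 0.93 ± 0.20 (adjusted p = 0.0263). Pou5f1, which encodes Oct4, differed by -0.15 (adjusted p = 0.387) and Nanog by -0.42 (adjusted p = 0.159, and 0.0490 with replicate number as a block). Without 1 array Nanog ran from -0.62 to -0.27, and it passed in 2 of 18 alternatives, the block included. Sox2 differed by -0.08 (adjusted p = 0.551) and by 0.02 with unscaled values, where the median of all genes was 0.11. The list was shifted down (camera adjusted p = 3.08e-06); with an estimated correlation the adjusted p = 0.256.

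**Figure D1:**
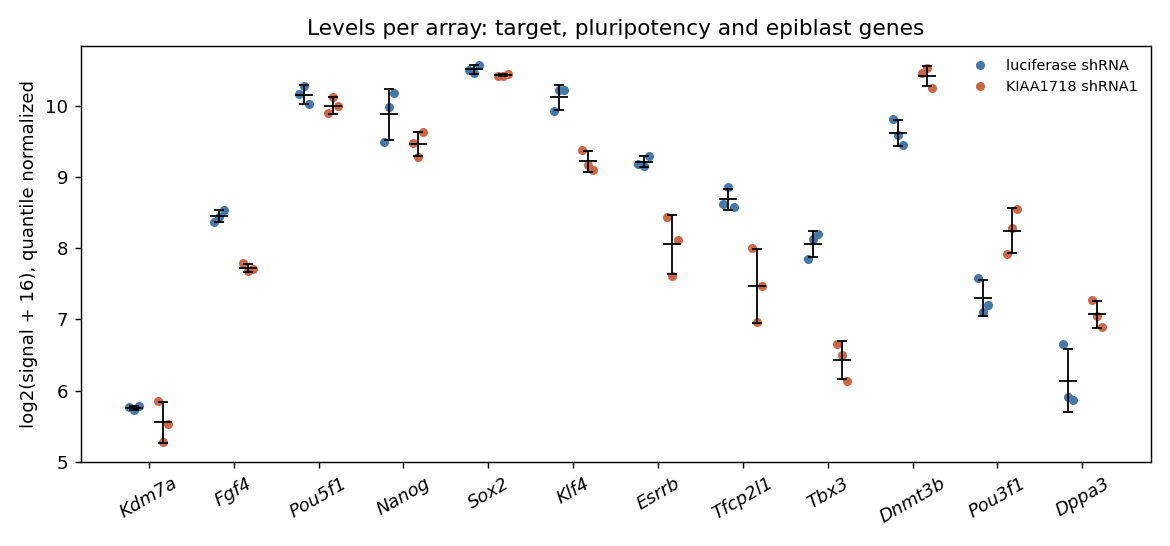
Normalized log2(signal + 16) of 12 genes on each of the 6 arrays, with luciferase shRNA in blue and KIAA1718 shRNA1 in orange; points are arrays, and black bars give the mean and SD of 3 arrays. Fgf4, Klf4, Esrrb, Tfcp2l1 and Tbx3 are lower and Dnmt3b, Pou3f1 and Dppa3 higher in all 3 knockdown arrays, while Kdm7a, Pou5f1 and Nanog overlap. Sox2 is also lower in all 3 knockdown arrays but did not pass the threshold.

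Genes of the primed epiblast, the later state that follows naive pluripotency, were higher. Of 18 members, 5 rose and none fell, and adjusted over the list alone 9 rose and 1 fell. The latter was Dnmt3a at -0.31 (adjusted p = 0.157 over all probe sets). Fgf5 at 0.84 (adjusted p = 0.0556) and Otx2 at 0.26 (adjusted p = 0.358) did not pass over all probe sets. The DNA methyltransferase gene Dnmt3b rose from 745 ± 91.5 to 1412 ± 100.1 and the transcription factor gene Pou3f1 from 137 ± 30.2 to 312 ± 90.2 (SD, n = 3). Pim2 rose by 1.06, and Fgf8 by 0.72 from a control signal of only 3.26 ± 0.902. The size for Fgf8 depends on the processing, from 0.25 to 1.95 across the alternatives. The camera adjusted p was 0.000103, and with an estimated correlation the adjusted p = 0.220.

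The targets of LIF and STAT3, the cytokine pathway that holds embryonic stem cells in self-renewal, were shifted down. Of 19 members 6 fell and 2 rose, with Tfcp2l1, Mras, Klf4 at -0.91 and Bcl3 at -0.86 the furthest, and adjusted over the list alone 9 fell and 2 rose. Its camera adjusted p was 0.00215, and with an estimated correlation the adjusted p = 0.379. Without the genes of chromosomes 1, 11, 12, 14, 19 and Y the list was not called (camera adjusted p = 0.0680), its median went from -0.14 to -0.07, and 3 of the 14 remaining members were lower and 2 higher; the median was -0.03 without luciferase replicate 1 and -0.22 without knockdown replicate 1, where the list was still called. The list of FGF and ERK signalling had 2 members higher and 3 lower of 32 (7 changed when adjusted over the list alone, 4 of them higher). The ERK-responsive transcription factor gene Etv4 fell by 0.65 with Fgf4, while the phosphatase gene Dusp4 rose by 0.58 with Fgf8. This list did not shift (camera adjusted p = 0.861), and its median of -0.04 and mean of 0.00401 differ in sign.

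The list of interferon and double-stranded RNA response genes was shifted up. Of 27 members 8 rose and none fell, and adjusted over the list alone 10 rose. The other 19 did not pass. Among them were the double-stranded RNA sensor genes Ifih1 at 0.15, Ddx58 at -0.12, Eif2ak2 at 0.10 and Oas1a at 0.07 (limma adjusted p of 0.615 or higher). The related Oasl2 rose by 0.57, from a control signal of only 5.28. Psmb8 rose by 1.37, the transcription factor gene Irf1 by 1.05, Ifi35 by 0.79 and the chemokine gene Cxcl10 by 0.76, the last from a control signal of 6.46 ± 3.99 (SD, n = 3). Across the alternatives Psmb8 ran from 0.66 to 2.19 and Cxcl10 from 0.29 to 1.73. The call of Cxcl10 was lost in 5 of 17 alternatives. The camera adjusted p was 0.00166, and with an estimated correlation the adjusted p = 0.220; the median was 0.10, and 0.07 to 0.18 without 1 array. Within the small RNA pathway none of 21 members passed (limma, none adjusted over the list alone), and the smallest p belonged to Prkra at 0.46 (adjusted p = 0.0913) and Tnrc6a at 0.28 (adjusted p = 0.222).

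Primitive endoderm genes, markers of the extraembryonic layer next to the epiblast, were lower. Of 27 members 6 fell and 1 rose, and adjusted over the list alone 10 fell and 2 rose. Srgn fell by 1.07, the transcription factor gene Sox7 by 0.84 and the laminin gene Lamc1 by 0.84, whereas the homeobox gene Rhox5 rose by 1.11. Sox7, at a signal of 13.6 in knockdown cells, ran from -1.42 to -0.38 across the alternatives. The transcription factor genes Gata6 at -0.31, Gata4 at -0.24 and Sox17 at -0.03 did not pass (limma adjusted p of 0.428 or higher). Their control signals were low, at 20.8, 11.9 and 17.2. The camera adjusted p was 0.00107, and with an estimated correlation the adjusted p = 0.256. Markers of embryonic fibroblasts, cells often used as feeders, varied between arrays alongside: the mean of 34 members was 7.67, 8.46 and 8.46 (log2) on control replicates 1, 2 and 3 and 7.54, 7.93 and 7.97 on knockdown replicates 1, 2 and 3, a difference of -0.38 (exact p = 0.3). None of the 34 passed (limma, none adjusted over the list alone), with Thy1 at -0.62 (adjusted p = 0.0574) and the collagen gene Col1a1 at -1.53 (adjusted p = 0.0714) closest, while with replicate number as a block 15 were lower, those 2 included. The fibroblast list had a camera adjusted p of 3.1e-05 with a median of -0.35, and with an estimated correlation the adjusted p = 0.523; the median was -0.60 to -0.19 without 1 array. With the fibroblast mean as a covariate, 3 primitive endoderm members were lower and 1 higher, and that list's median went from -0.24 to -0.10 with a camera adjusted p of 0.0151.

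Among other lineages, the keratin genes Krt8, Krt18 and Krt19 of the trophectoderm list rose by 1.28, 1.02 and 1.82, its other keratin gene Krt7 differed by 0.10 (adjusted p = 0.834), and the growth factor gene Bmp4 fell by 1.00. With 3 of 19 members higher and 1 lower (the same counts adjusted over the list alone) the trophectoderm list did not shift (camera adjusted p = 0.176). In the neuroectoderm list Fabp7 rose by 0.94 and Neurod1 by 0.68 and Gbx2 fell by 0.55, 3 of 21 members changed (5 higher and 2 lower adjusted over the list alone, 5 changed with replicate number as a block), and the camera adjusted p was 0.403. The neurofilament gene Nefl rose by 0.96 and Dpysl3 fell by 0.56 among 19 neuronal genes (2 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.211). Dpysl3 (limma adjusted p = 0.0458) lost its call in 14 of 18 alternatives. Bmp4 and Fgf8 were the members that changed among 23 mesoderm genes (1 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.444), where the median of -0.000679 and the mean of 0.0463 differ in sign. The meiotic regulator gene Stra8 fell by 0.95 and Rnf17 by 0.66 among 21 germline genes (4 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0523, under 0.05 in 9 of 19 alternatives). No Hox gene of 22 passed (limma, none adjusted over the list alone), the nearest being Hoxc10 at -0.49 (adjusted p = 0.0943) and Hoxc8 at -0.34 (adjusted p = 0.191). That list still had a camera adjusted p of 0.0297 with a median of -0.19, and with an estimated correlation the adjusted p = 0.256. The Hox call was lost in 6 of 19 alternatives, among them the fibroblast covariate (adjusted p = 0.19, median -0.14) and leaving out chromosomes 1, 11, 12, 14, 19 and Y (adjusted p = 0.0656, median -0.16); without 1 array the median was -0.21 to -0.10. None of 7 genes of the 2-cell-like state passed (none adjusted over the list alone, camera adjusted p = 0.938), with Zfp352 at 0.14 and Sp110 at -0.11. In the blood and endothelium list the receptor gene Tek rose by 0.76 and Kdr differed by 0.41 (adjusted p = 0.167), with 1 of 15 changed (1 higher adjusted over the list alone, camera adjusted p = 0.401). The control signals of Tek and Fabp7 were low, at 11.9 and 10.3. Across the alternatives Tek ran from 0.34 to 1.30 and Fabp7 from 0.41 to 1.64.

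In the machinery of H3K9 and H3K27 methylation, the marks KIAA1718 acts on, the H3K9 methyltransferase gene Ehmt2 fell from 419 ± 47.0 to 289 ± 2.81 (SD, n = 3, limma adjusted p = 0.00392). The heterochromatin protein gene Cbx1 rose by 0.54 and the Y-linked demethylase gene Uty by 0.99. In all, 3 of 38 members changed (3 higher and 1 lower adjusted over the list alone), and the list did not shift (camera adjusted p = 0.861). Among imprinted genes, Mest rose by 1.25, Nnat by 0.86 and Magel2 by 0.85, and Mirg fell by 0.62. Of 29 members 4 rose and 1 fell (5 and 1 adjusted over the list alone), with a camera adjusted p of 0.0516, and 0.0264 with replicate number as a block; 9 of 19 alternatives, the block included, called the list.

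Signalling lists for Wnt and for BMP and TGF-beta did not shift, though members changed. Among 25 BMP and TGF-beta targets Inhbb fell by 1.96, Bmp4 by 1.00 and Smad7 by 0.51 (3 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.332). Smad7 lost its call in 12 of 18 alternatives, while Inhbb and Bmp4 kept theirs in all 17. Of 18 Wnt targets Tcf7l2, Fzd7 and Myc fell, by 0.79, 0.72 and 0.46, and Sp5 rose by 0.70 (3 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.631). Myc lost its call in 10 of 18 alternatives, Sp5 in 5 of 18, and Tcf7l2 and Fzd7 in 4 of 17 each. The Notch list was shifted up with a median of 0.27 and 13 of 15 members above 0; the ligand gene Dll3 rose by 0.68 (2 members higher adjusted over the list alone) and Jag1 differed by 0.53 (adjusted p = 0.0830). Its camera adjusted p was 0.00767, and with an estimated correlation the adjusted p = 0.256. The list median was 0.15 to 0.31 without 1 array. Dll3 lost its call in 5 of 18 alternatives.

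Oxidative phosphorylation genes were lower by small amounts. Of 35 members 6 fell and none rose, and adjusted over the list alone 9 fell. Sdhc fell by 0.47, and the complex I genes Ndufs1, Ndufv1 and Ndufb3 by 0.43, 0.43 and 0.42. Of 17 alternatives, Sdhc lost its call in 10, Ndufs1 in 4, Ndufv1 in 9 and Ndufb3 in 11. The camera adjusted p was 0.00166, and with an estimated correlation the adjusted p = 0.431. Without the genes of chromosomes 1, 11, 12, 14, 19 and Y, 1 of the 28 remaining members was lower, with a median of -0.06 and a camera adjusted p of 0.0377; with the fibroblast covariate no member passed and the median was -0.08, as in the main setting (camera adjusted p = 0.0123). Without 1 array the median was -0.17 to -0.04. With unscaled values it was 0.02, against 0.11 for all genes, and the list was still called lower (camera adjusted p = 0.0413). Cholesterol synthesis had 1 of 20 changed, Idi1 at 0.39, with Fdps at 0.44 (adjusted p = 0.0593, and 0.0258 with replicate number as a block), 4 higher adjusted over the list alone and a camera adjusted p of 0.0638, under 0.05 in 4 of 19 alternatives. None of 30 hypoxia and glycolysis genes passed (none adjusted over the list alone, camera adjusted p = 0.945), with Aldoc at 0.51 (adjusted p = 0.0509, and 0.0349 with the block) and Ankrd37 at 0.47 (adjusted p = 0.0980). None of 22 ribosomal protein genes passed (none adjusted over the list alone, camera adjusted p = 0.353), with Rps7 at -0.12 and Rpl11 at -0.15.

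The stress and growth lists did not pass in the main setting. The p53 targets Ddit4, Trp53inp1 and Ccng1 rose by 0.62, 0.54 and 0.34, 3 of 29 members (3 higher and 2 lower adjusted over the list alone, 3 higher and 1 lower with replicate number as a block, camera adjusted p = 0.185). In the cell cycle list Top2a rose by 0.38 and E2f1 differed by -0.46 (adjusted p = 0.0548, and 0.0456 with replicate number as a block); 1 of 37 changed (5 higher and 4 lower adjusted over the list alone, 4 higher and 3 lower with the block), the camera adjusted p was 0.738, and the median of -0.01 and mean of 0.02 differ in sign. Ddit4 was the changed member among 31 genes of the integrated stress response, with Slc7a1 at -0.44 (adjusted p = 0.0647, and 0.0305 with the block; 1 higher and 3 lower adjusted over the list alone, 1 higher and 2 lower with the block, camera adjusted p = 0.143). That list was called in 3 of 19 alternatives, with a median of -0.13 and a camera adjusted p of 0.0151 under the fibroblast covariate. None of 22 endoplasmic reticulum chaperone genes passed, with Canx at 0.33 (adjusted p = 0.0702, and 0.0468 with the block) and Manf at 0.30 (adjusted p = 0.0973; 3 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.185). In all, 9 of the 29 lists were called at the preset correlation, 3 higher and 6 lower, and 0 with an estimated correlation, where 4 had an unadjusted p under 0.05; 10 were called by fry, which asks whether the members move on balance one way. Of the 9, fry did not call oxidative phosphorylation (adjusted p = 0.101) or fibroblasts (adjusted p = 0.347), and it called neurons (adjusted p = 0.00540), cholesterol synthesis (adjusted p = 0.0140) and imprinted genes (adjusted p = 0.0245), which camera did not. With replicate number as a block, camera called the 9 and imprinted genes.

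**Figure D2:**
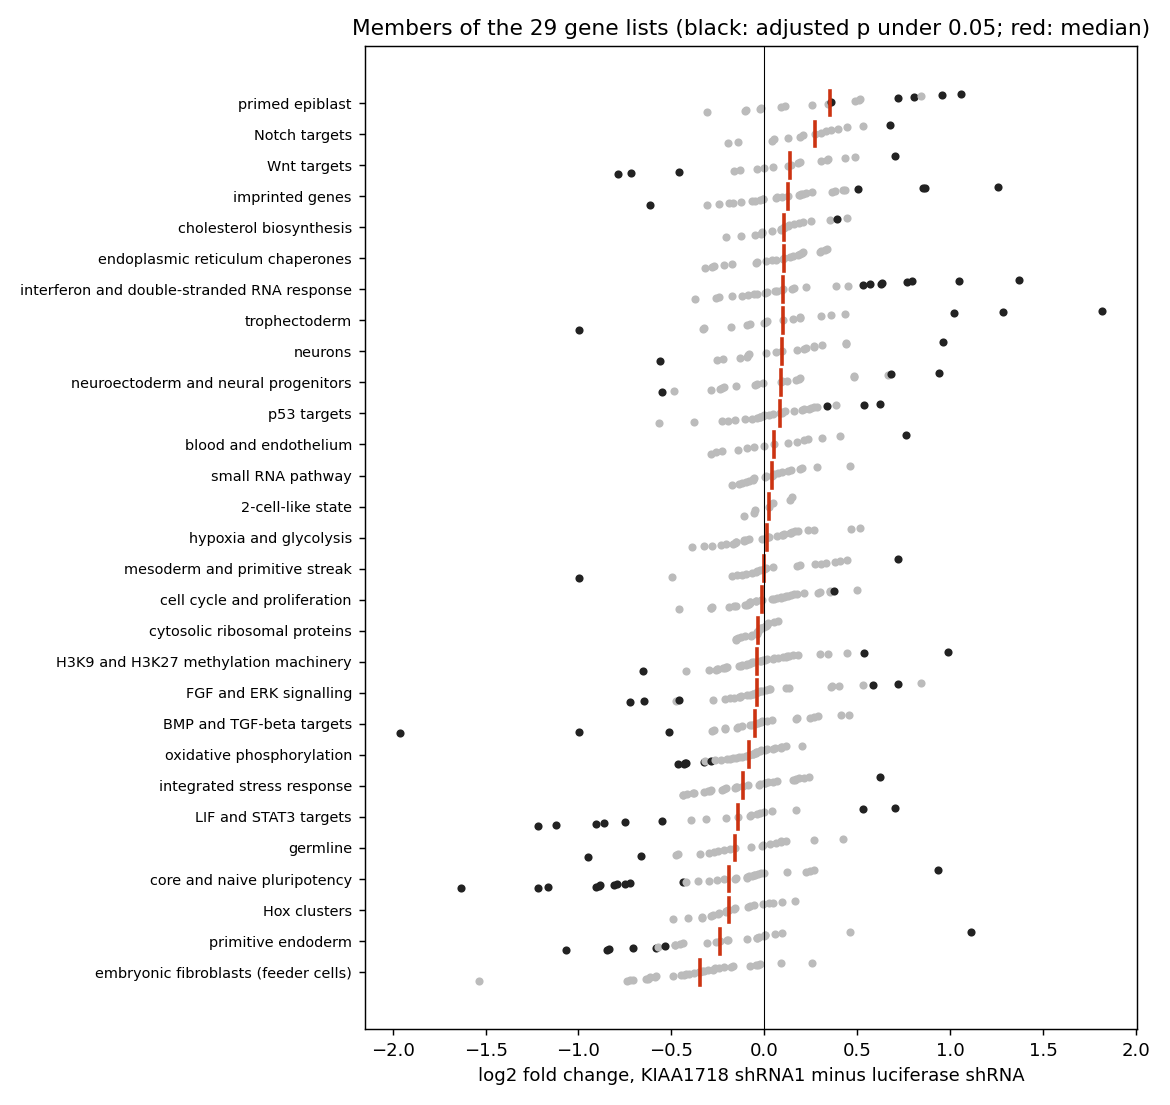
Log2 fold change, KIAA1718 shRNA1 minus luciferase shRNA, of each measured member of the 29 gene lists, ordered by median; black points have an adjusted p under 0.05, grey points do not, and red lines are medians. The median is highest for the primed epiblast at 0.35 and lowest for embryonic fibroblasts at -0.35, where no point is black.

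Genes of whole chromosomes shifted together. Median log2 differences were -0.13 for the 719 genes of chromosome 1, -0.14 for the 449 of chromosome 12, -0.15 for the 431 of chromosome 14 and -0.15 for the 457 of chromosome 19, and 0.13 for the 1048 of chromosome 11. With an estimated correlation the camera adjusted p-values were 0.0109, 0.0193, 0.0109, 0.0109 and 0.0495. Relative to each array's mean, the genes of chromosome 14 lay at 0.266 ± 0.00879 in controls and 0.120 ± 0.00722 in knockdown cells (SD, n = 3, exact p = 0.1, the smallest possible). Chromosome 13, with a median of 0.06, passed at the preset correlation (adjusted p = 0.0472) and not with an estimated one (adjusted p = 0.272), and the medians of the other 14 chromosomes ran from -0.03 to 0.05. The 5 chromosomes held 234 of the changed genes, 38.2%, and 24.4% of those tested. Many named genes lie on them, among others Esrrb, Tfcp2l1, Inhbb, Fzd5, Krt19, Igfbp3 and Irf1. All the oxidative phosphorylation genes named above lie there, Sdhc, Ndufs1 and Ndufb3 on chromosome 1 and Ndufv1 on chromosome 19. Against the shift of their chromosome, Cobl and Etv4 on 11 fell, and Nefl on 14 and Fgf8 on 19 rose. On the Y chromosome Eif2s3y and Uty rose, and Uba1y at 0.37 (adjusted p = 0.228) and Orly at 0.21 (adjusted p = 0.399) did not pass. Without these 5 chromosomes and Y, 310 genes changed, 200 of them higher; 6 pluripotency members fell and 1 rose, and 4 primed epiblast members rose.

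**Figure D3:**
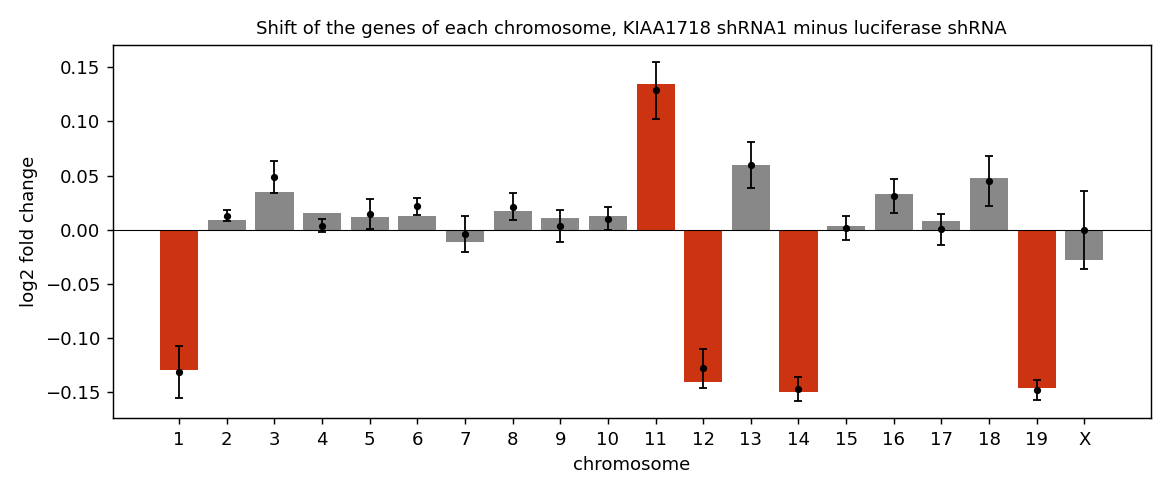
Bars give the median log2 fold change, KIAA1718 shRNA1 minus luciferase shRNA, of the genes of each chromosome; points give the difference of the chromosome's mean relative to each array's mean, with error bars of the combined SD of 3 and 3 arrays. The chromosomes called with an estimated correlation are red: 1, 12, 14 and 19 lie between -0.13 and -0.15 and chromosome 11 at 0.13.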

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

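The quantile normalization of the main setting, the fibroblast covariate and the settings without 6 chromosomes were chosen after seeing the data; the unscaled values are the setting first planned. The count of 612 genes and 991 probe sets moved by over 1.5 times without a filter (197 and 290), with unscaled values (364 and 576), without the intensity trend (394 and 634), with the replicate block (1005 and 1684), at a fold of at least 1.5 (356 and 585), with the fibroblast covariate (243 and 388) and without chromosomes 1, 11, 12, 14, 19 and Y (310 and 504); the mean of all probe sets gave 953 genes. Leaving out an array in turn gave 167 to 526 genes and 262 to 829 probe sets. More tests without a filter and fewer arrays account for part of the loss by construction; otherwise the cause was not tested. The covariate kept 225 of the 612 genes and the sign of all 612; the median SE of those genes was 0.126 without it and 0.150 with it. Where tested, the 74 named genes past the threshold kept their direction in all 1301 values from the alternatives and their side of the threshold in 1088. Besides those given with the results, the calls lost most often were Ccng1, Gbx2 and Mirg, in 10, 9 and 7 of 17. Idi1, Dusp4, Dppa3 and Ddit4 lost theirs in 10, 9, 8 and 8 of 18. Kdm7a stayed on its side of the threshold in every alternative. The number of chromosomes called stayed at 5 or 6, and chromosomes 1, 11, 12, 14 and 19 were called in every alternative that kept them. The number of lists called was 0 with an estimated correlation and 8 to 12 otherwise. Of the 9 called lists, LIF and STAT3 targets and Hox were lost without the 6 chromosomes, and Hox and the fibroblast list itself with the covariate. Hox was also lost with the lowest 60% left out (adjusted p = 0.36) and without luciferase replicate 3 (0.092) or knockdown replicate 1 (0.0641). Germline, imprinted, cholesterol and integrated stress response lists were called in 9, 9, 4 and 3 alternatives of 19. Among lists, chromosomes and genes named by the rule, the replicate block changed no calls other than those given with the results. It also changed counts within lists. Higher and lower members were then 2 and 12 for pluripotency and 7 and 0 for primed epiblast. FGF and ERK signalling had 4 and 3, primitive endoderm 1 and 7, LIF and STAT3 targets 2 and 7, and oxidative phosphorylation 0 and 7. H3K9 and H3K27 methylation had 3 and 1, imprinted genes 5 and 1, mesoderm 1 and 2, and BMP and TGF-beta 1 and 3.

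Directions turned only where neither setting passed, except for the fibroblast list, whose median was 0.0330 with its own mean as covariate, as built. Unscaled values put the median of all genes at 0.107, which moves signs by itself: Sox2 was at 0.0181, below that median, and list medians were 0.0912 for FGF and ERK signalling and 0.0854 for H3K9 and H3K27 methylation, -0.0153 and -0.0211 relative to all genes (camera direction up for both, adjusted p = 0.93). The medians of mesoderm, cell cycle, integrated stress response, ribosomal protein, BMP and oxidative phosphorylation lists were likewise under 0 in the main setting and over 0 unscaled, with the camera direction unchanged; the called one, oxidative phosphorylation, went from -0.0803 to 0.0190, which is -0.0875 relative to all genes. List directions are those of camera, which can differ from the median printed. The 2-cell-like list had -0.00137 without a filter, -0.00365 with median centring and -0.0983 to 0.0923 without an array. Leaving out the lowest 60% gave -0.00436 for mesoderm and 0.0238 for Wnt. Hypoxia and glycolysis had 0.0213 with median centring, 0.0163 with the mean of all probe sets, -0.0497 with the covariate, 0.0151 without the 6 chromosomes and -0.0535 to 0.0455 without an array. Cell cycle had -0.0257 with the covariate, -0.0137 without the 6 chromosomes and -0.0211 to 0.0217 without an array. Without an array FGF and ERK signalling had -0.0550 to 0.0118 and H3K9 and H3K27 methylation -0.0705 to -0.0106. Low signals limit these arrays: median signals per array, 9.58 to 13.3, lie below the pseudocount of 16.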

Other observations

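The values of this paragraph were picked out after they were seen. Of 9 measured interferon-inducible GTPase genes, 6 rose and none fell. Beyond Gbp2, Gbp2b and Gbp3 these were Irgm1 at 1.16, Gbp7 at 1.11 and Igtp at 0.90, while Irgm2 was at 0.25 (adjusted p = 0.307), Iigp1 at 0.17 and Ifi47 at 0.06. Around Snhg14 on chromosome 7, by gene order in GRCm38.p6, 11 genes were measured, 3 rose and none fell: Snhg14, Atp10a by 0.91 and Magel2 by 0.85. Snrpn at 0.38 (adjusted p = 0.283), Gabra5 at 0.30 (adjusted p = 0.264), Ube3a at 0.13, Ndn at 0.09, Oca2 at 0.05, Peg12 at -0.01, Herc2 at -0.03 and Mkrn3 at -0.13 did not pass. Of 15 measured keratin genes Krt8, Krt18 and Krt19 rose and none fell; the other 12, among them Krt42 at 0.03 with a signal of 101 ± 18.7 in controls and 112 ± 7.67 in knockdown cells (SD, n = 3), did not pass. Unscaled, Herc2 was at 0.08, Peg12 at 0.05 and Krt17 at 0.04 against -0.04 in the main setting, and no other sign of these genes turned.

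The tests on the chromosomes and on Kdm7a, the comparison of crossed array pairs, and the splits for probe sets and genes were chosen after the values were seen. With 10 splits of the 6 arrays the share of splits can never fall under 0.05. The real split gave 991 probe sets, 612 genes, 9 lists and 6 chromosomes, and 1 split, the real one, gave as many of each; the highest of the other 9 gave 0, 0, 6 and 5. At an unadjusted p under 0.05 limma gave 2802 genes for the real split and 152 to 634 for the others. The 3 other splits that part all 3 same-numbered pairs gave 0 genes with and without the replicate block, 0 to 4 lists and 4 or 5 chromosomes. Each of the other splits still sets 2 arrays of a group against 1 of the same group. The difference between the groups then adds to the spread within each side, which lowers the counts of probe sets and genes. Part of it also stays between the sides, so these splits do not give the counts expected by chance.

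Chromosomes 1, 12, 14 and 19 were lower and chromosome 11 higher by similar amounts. A few strongly changed genes are argued against, since at least 71.7% of the genes of each of the 5 chromosomes lay on the shifted side. In the unscaled values each chromosome still differed from all other genes by at least 0.135 (log2), so the quantile normalization did not make the shift. A scale factor of a whole array moves all genes nearly alike, so this difference cannot test it. A candidate explanation is a difference in chromosome copy number in part of the cells of either population: all 50 segments, 10 per chromosome by gene order, had medians on the shifted side, from 0.0353 to 0.249 in size. The cell populations are the treatment groups, so an effect of the shRNA spread over whole chromosomes stays open, and no DNA was measured.

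Kdm7a did not fall past the threshold. For 1 of the 3 tested probe sets, with a control signal of 32.6 ± 1.76 (SD, n = 3), array noise hiding a halved signal is argued against, since its interval ends 0.141 (log2) above the difference that halving gives, and at least 0.0269 above without any 1 array. For the brightest this cannot be told apart from no loss, because the margin of 0.0757 becomes -0.0655 without 1 array, and for the dimmest halving lies inside the interval (-0.174). Signal from background or another transcript could mask a loss, and cannot be told apart from an absent knockdown, because the brightest probe set lies at the 67.1th percentile of signals, neither low nor high. A loss of protein without loss of this transcript was not measured.

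Fibroblast markers varied between arrays. The list had been written for feeder cells, 4 of its 34 tested genes are in another list, and GFP sorting would remove uninfected feeders. A single source of such RNA in varying amount is a candidate explanation. The first principal component of the list took 85.0% of its variance, at the 100th percentile of 10000 matched lists (median 52.2%). Those lists were random genes matched on mean signal only, so any genes that vary together would rank high. The percentile shows that the members moved together, and cannot tell a single RNA source from another shared change. The member with the highest mean signal, Acta2, had signals of 1516, 2194 and 2460 on control replicates 1, 2 and 3. On knockdown replicates 1, 2 and 3 they were 1573, 2061 and 2059. With the list mean as covariate 100% of the 612 changed genes kept their sign and at least 50% of their log2 difference, although 243 genes passed. That outcome was nearly assured by the choice of the genes. The list mean had an SD of 0.456 in controls against a difference of -0.384 between the groups (log2). Genes that follow it then rarely pass, and none of the 34 members did. Varying fibroblast RNA is argued against as the source of the pairing of arrays 2 and 3, whose same-numbered correlations exceed the crossed ones by 0.145. For replicate 1 it stays open. The planned test, regressing out the list mean, gave -0.996, -0.0458 and 0.0215 for pairs 1, 2 and 3. That test decides nothing, because the regression by itself forces -0.996, -0.101 and -0.133.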
